A study of Methylibium petroleiphilum PM1 with 6 samples.

How the data were processed

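Total RNA from cultures of Methylibium petroleiphilum PM1 grown aerobically on MTBE or ethanol was turned into Cy3-labelled cDNA and hybridized to NimbleGen 1-colour arrays, per the labels' protocols. The replicates of each group are separate biological replicates per the labels. Group membership was taken from the sample labels, with 3 samples per group.

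Values came in 3 forms. Each array has a file of mean intensity per gene over its 1 to 9 probes, on a linear scale and without normalization, per the file headers and values, with 3 values per gene that were averaged on the log2 scale. For 11 genes the intensity stood in the mismatch column, so the column that holds the sum was used. Each array also has a file of log2 values that the file headers name RMA, again with 3 deposited values per gene. The series table has 1 log2 value per gene and sample, as deposited by the authors. Its sample medians lie close together, 7.60 to 7.62 on ethanol and 7.73 to 7.74 on MTBE. The SD over genes differs with the group (1.62 to 1.70 and 1.11 to 1.16), so the 2 groups do not share 1 distribution in it. Whether their levels can still be compared could not be tested. RMA and limma are named in the submitters' processing notes, and their versions, their settings and how the 2 arrays of an ethanol sample enter the series table are not given in the sources used here. RMA corrects background and forces the arrays processed together to 1 distribution, so levels of arrays processed apart are not on a common scale. That the values of the series table are log2 was read from their range, and whether they were centred stays unknown. Its columns rise with the RMA values of their own arrays. Across genes r was 0.934 to 0.940 in MTBE, 0.986 to 0.990 for set 1 of the ethanol arrays and 0.817 to 0.847 for set 2. These correlations concern levels and do not test the direction of MTBE minus ethanol.

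The design fixed before the data were examined used the RMA files per array, averaged per sample. Their values show that the arrays had been normalized in 3 separate sets of 3, each within 1 group, so that the scale differs with the group. Fitted as written, that design gave 17 genes higher and 3940 lower with a median log2 fold change of -2.00. The separate scales were found before any test. The series table, planned as an alternative source, was made the main source instead, and this choice over the re-normalized arrays was settled after gene counts under these settings had been seen. Results under each source are therefore given in the closing section.

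Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate) on all 6 samples and 4006 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is MTBE minus ethanol, and a change of at least 2-fold has an absolute log2 fold change of 1 or more. No gene was filtered out. Contigs were tested with camera (preset correlation 0.01, and an estimated correlation) and with fry, adjusted over 31 contigs with at least 3 genes, and each contig median was set against 10000 random lists matched on level. Neighbouring genes are those next to each other in number on 1 contig, and runs are consecutive genes that each passed and changed by at least 2-fold in 1 direction. Shuffled gene orders were drawn in Python 3.11.15 with numpy 2.4.6, 100000 for the correlation between neighbours and 1000 for the runs.

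The steps were tested on simulated data for MTBE against ethanol with 4006 genes, of which 200 were changed. Of the genes changed 2-fold, 74% were recovered, and of those changed 4-fold 92%, while 9 unchanged genes were called and 0 calls had the wrong sign. The 1 shifted contig was found, 0 others were called, and 12 consecutive genes of a seeded run of 20 were found. The simulation drew each gene independently. It therefore cannot show how often contigs or runs are called when neighbouring genes move together.

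The rule for named genes took the genes with the largest rise and fall among those that passed with all 3 MTBE samples on 1 side of the ethanol samples. Since the files pair no identifier with a name, 2 identifiers per direction are given. For the same reason the 35 gene lists fixed beforehand (4 by locus tag and 31 by product text), the comparison of megaplasmid and chromosome and the known MTBE pathway genes were not analysed here. Contigs and runs of neighbouring genes took their place and were chosen after the data were examined. The contigs are those of the draft assembly in the files, and their place on the chromosome or the megaplasmid is not given in the sources used here.

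Alternatives covered the source of the values, background correction, centring and quantile normalization, the choice among the 2 arrays of each ethanol sample, all arrays with the sample as a random block, the replicate number as a block, filters on dim genes and on genes with under 4 probes, the moderation, array weights, a test against a fold of 1.2 and leaving out each sample in turn. Settings that pick arrays cannot act on the series table and were run on quantile-normalized intensities. The 2 sets of ethanol arrays are named from the RMA medians and carry no label of their own, and each set was also compared with the other, with the sample as a block. Intensities were background corrected in 1 alternative (normexp, offset 50). In the other settings they were not, and uncorrected background narrows fold changes.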

Results

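Methylibium petroleiphilum PM1 is an aerobic bacterium that can use methyl tert-butyl ether (MTBE), a fuel oxygenate, as its sole source of carbon and energy. Its transcripts were measured on NimbleGen 1-colour expression arrays after growth on MTBE or on ethanol, and cells were taken in the middle of exponential growth. Each carbon source had 3 biological replicates, so 6 samples entered the comparison. The 3 ethanol samples had 2 arrays each and the 3 MTBE samples 1 array each, 9 arrays in all. The ethanol arrays form 2 sets, each with 1 array of every ethanol sample, that were normalized apart by the authors, as their values show. The arrays covered 4006 predicted genes on 33 contigs of a draft assembly, with 1 to 9 probes per gene and a median of 7. The main values are the log2 gene values of the deposited table of the whole series. Their sample medians were 7.60 to 7.62 in ethanol and 7.73 to 7.74 in MTBE. The SD over genes was 1.62 to 1.70 in the ethanol samples and 1.11 to 1.16 in the MTBE samples, so values on ethanol spanned a wider range. The number of arrays limits the precision, and the files carry no detection call per gene. Genes are given by the identifiers, contigs and gene numbers of the files, which pair none of the 4006 identifiers with a gene name.

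The main comparison asked which genes differ in transcript level between growth on MTBE and growth on ethanol. With limma, 1421 genes were higher on MTBE and 1122 were lower at an adjusted p under 0.05, so 63.5% of the genes tested changed. MTBE and ethanol arrays share no array set, so a difference between sets cannot be told apart from one between carbon sources. Between the 2 ethanol sets, which carry the same sample labels, 1208 genes differed in quantile-normalized intensities. That difference (set 2 minus set 1) had a correlation of 0.430 across genes with MTBE minus ethanol, although set 1 enters both. In the table as deposited, changes of at least 2-fold between MTBE and ethanol went mostly downward, with 446 genes higher and 798 lower on MTBE. At 4-fold or more the counts were 61 higher and 335 lower, and at 8-fold or more 9 higher and 120 lower. The 3 MTBE values lay wholly above or below the 3 ethanol values for 2936 genes (73.3%), against 10% by chance. The balance of directions depended on the scaling and on which genes were tested. Of the genes changed by at least 2-fold, 35.9% were higher on MTBE in the table as deposited, 28.0% after each sample was centred on its median and 50.2% after quantile normalization of the table. The last setting gave 580 genes at least 2-fold higher and 576 lower. In quantile-normalized intensities these counts were 207 and 220, and against set 2 of the ethanol arrays 131 and 158. The median change of all genes was +0.16 on the log2 scale in the table as deposited, and after centring 1066 genes were higher and 1241 lower. Without the dimmest 25% of genes 852 were higher and 1085 lower, and a test against a fold of 1.2 gave 890 higher and 930 lower.

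**Figure D1:**
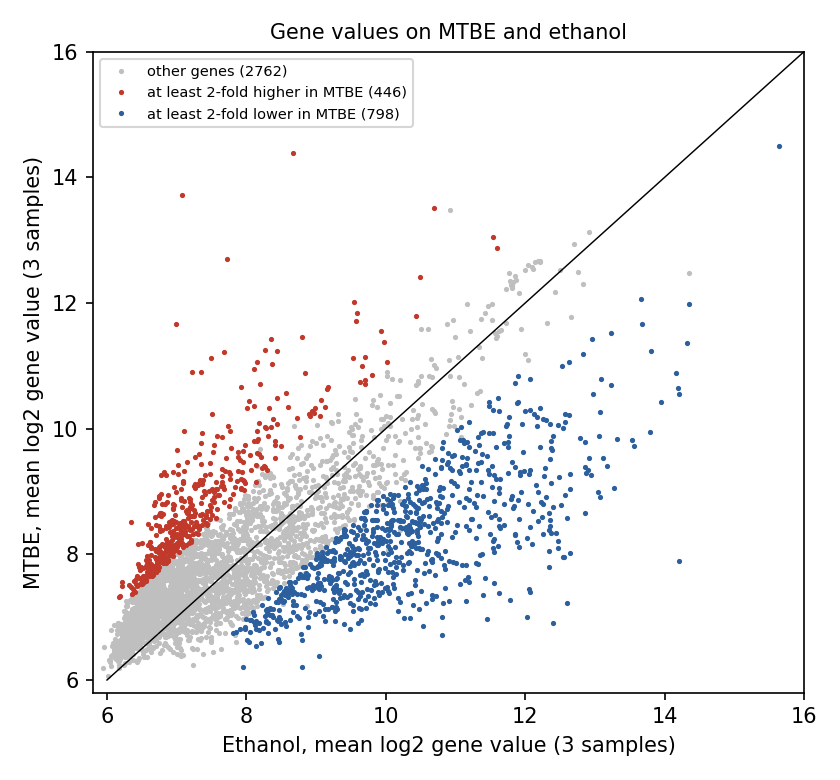
Mean log2 gene value of the 3 ethanol samples (horizontal axis) against that of the 3 MTBE samples (vertical axis), 1 point per gene, with the line of equality. The 446 genes at least 2-fold higher and the 798 at least 2-fold lower on MTBE (limma, adjusted p under 0.05) are coloured.

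In the table, the gene with the largest rise on MTBE was LLNL0001S00003083, gene 3083 on contig 578. Its log2 value was 7.07 ± 0.338 (SD, n = 3) on ethanol and 13.7 ± 0.158 (SD, n = 3) on MTBE, a log2 fold change of 6.64 with a standard error of 0.195 and a limma adjusted p of 1.0e-05. It lay at the 34.4th percentile of all genes on ethanol and at the 99.95th on MTBE, and it rests on 3 probes. Whether its level on ethanol is above background is unknown, so the size of its rise is uncertain and is given on the log2 scale only. The second largest rise was that of LLNL0001S00000481, gene 481 on contig 563, which went from 8.67 ± 0.353 to 14.4 ± 0.055 (SD, n = 3 each), or 52.5-fold. The order and size of these 2 rises depended on the source of the values. In quantile-normalized intensities the log2 fold change was 3.66 for LLNL0001S00003083 and 3.96 for LLNL0001S00000481, and against set 2 of the ethanol arrays 2.99 and 3.53. In the RMA values quantile normalized once more it was 6.09 and 5.84, in the order of the table. The largest fall in the table was that of LLNL0001S00003400, gene 5403 on contig 579, from 14.2 ± 0.096 on ethanol to 7.89 ± 0.024 on MTBE (SD, n = 3 each). Its log2 fold change was -6.31 with a standard error of 0.113, and its limma adjusted p was 1.0e-06. On MTBE it lay at the 55.6th percentile of all genes. Whether that level is above background is unknown, so the size of this fall is given on the log2 scale only. In quantile-normalized intensities its log2 fold change was -3.19, and against set 2 of the ethanol arrays -2.31. The next gene on the same contig, LLNL0001S00003401 (gene 5404), fell by 5.50 on the log2 scale. On MTBE it lay at the 13.1th percentile of all genes, and whether so dim a level is above background is unknown. The size of its fall is therefore uncertain and is given on the log2 scale only. These 2 neighbours belong to a run of 6 consecutive genes, 5402 to 5407, that were each at least 2-fold lower, with a mean log2 fold change of -3.71. In quantile-normalized intensities with the second listed array of each ethanol sample, gene 5404 no longer passed (log2 fold change -1.07, limma adjusted p = 0.128), while over the other settings its adjusted p was 1.6e-06 to 0.021. It changed by -2.56 against set 1 of the ethanol arrays and by -0.65 against set 2 (limma adjusted p = 0.021).

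Genes that changed lay together on the draft contigs. Across 3973 pairs of neighbouring genes, the correlation of the log2 fold changes was 0.536, whereas 100000 random gene orders gave at most 0.077. The permutation p was 1e-05, the smallest these shuffles can give. The correlation was lower after quantile normalization, 0.393 in the table, 0.359 in the RMA values and 0.352 in the intensities, and 0.316 in the intensities against set 2 of the ethanol arrays. Runs of at least 5 consecutive genes that were each at least 2-fold lower numbered 29 and held 227 genes, and 1000 shuffled orders gave at most 5 such runs and none longer than 9 genes. Runs of genes each at least 2-fold higher numbered 2 and held 12 genes. Shuffled orders gave at most 1 such run, although its length reached 7 genes, the length of the longest observed. Runs were counted only in the table as deposited, where 446 genes at least 2-fold higher and 798 lower could enter them. After quantile normalization of the table these were 580 and 576, so the contrast between runs of falls and of rises may depend on the scaling. Genes are not independent replicates, and deviations of single replicates from their group mean were also correlated between neighbouring genes in the table, with r from 0.143 to 0.388, a range that holds all but the first of these lower values. The difference between the 2 ethanol array sets, which carry the same sample labels, gave 0.378 between neighbours in quantile-normalized intensities. Grouping of this strength therefore also arose without a contrast of carbon sources.

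The longest run of falls covered genes 1906 to 1929 of contig 574, 24 genes with a mean log2 fold change of -3.43. Gene 1930 changed little (log2 fold change -0.26, limma adjusted p = 0.344), and the next 17 genes, 1931 to 1947, fell again with a mean of -3.40. The mean log2 value of genes 1906 to 1929 was 12.3 ± 0.146 on ethanol and 8.83 ± 0.233 on MTBE (SD, n = 3 each). Of the 42 genes from 1906 to 1947, 41 fell at least 2-fold. A run of 21 genes on contig 569, genes 1143 to 1163, had a mean log2 fold change of -2.18. Unnormalized intensities brought to 1 distribution gave smaller changes for these 3 runs. In them the mean of genes 1906 to 1929 was -1.74 against set 1 of the ethanol arrays and -1.54 against set 2, and that of genes 1931 to 1947 was -1.88 and -1.34. The mean of the run on contig 569 was -0.88 against set 1 and -0.21 against set 2. Further runs of falls held 11 genes on contig 578 (3085 to 3095, mean -2.29), 11 genes on contig 579 (5759 to 5769, mean -2.94) and 10 genes on contig 577 (2670 to 2679, mean -3.36). Gene 3083, the gene with the largest rise in the table, lies 2 numbers before the run of falls on contig 578. Both runs of rises were on contig 562. Genes 401 to 407 had a mean log2 fold change of 2.29 and genes 409 to 413 a mean of 1.36. For genes 401 to 407 the mean log2 value was 7.94 to 8.12 in the ethanol samples and 10.7, 10.6 and 9.63 in MTBE samples 1, 2 and 3. In the intensities the mean of genes 401 to 407 was 1.36 against set 1 and 0.99 against set 2, and that of genes 409 to 413 was 0.64 and 0.26. In the RMA values quantile normalized once more, the means of these 2 runs of rises were 3.22 and 1.15.

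**Figure D2:**
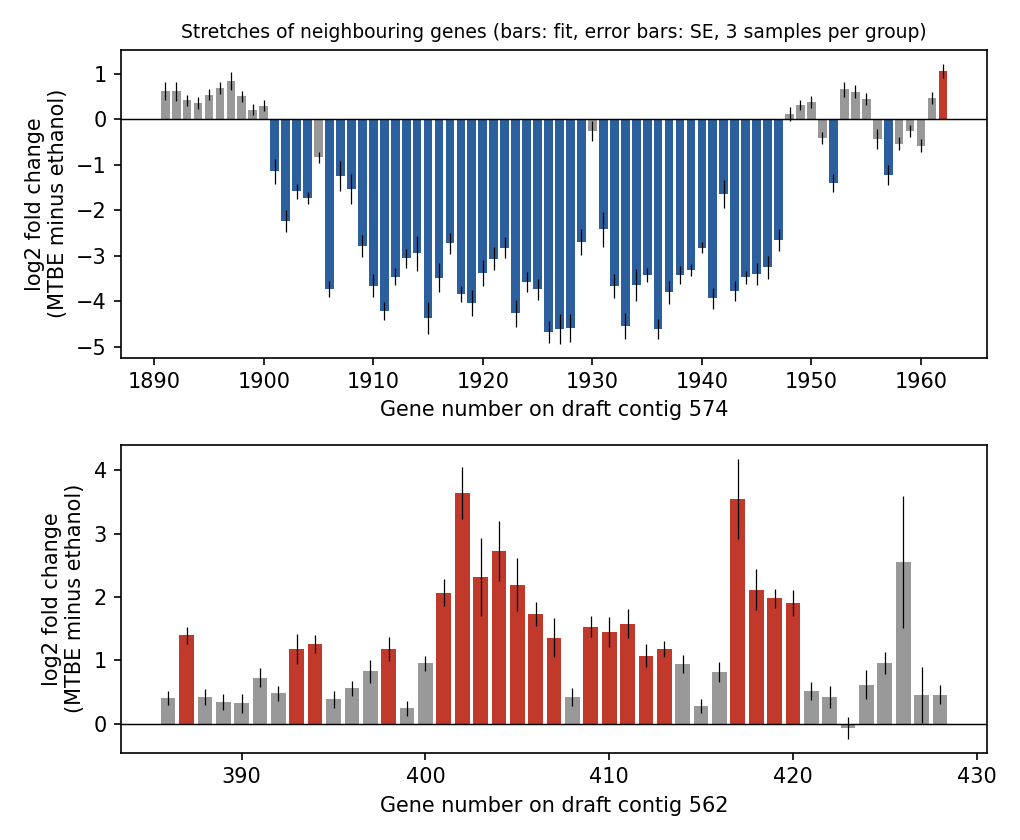
Log2 fold change (MTBE minus ethanol) of consecutive genes around the longest runs on contig 574 (top) and contig 562 (bottom), with the gene number on the horizontal axis. Bars are fitted values of 3 samples per group, error bars are standard errors, and coloured bars changed by at least 2-fold (limma, adjusted p under 0.05): 41 of genes 1906 to 1947 fell, and genes 401 to 407 and 409 to 413 rose.

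Genes of some contigs moved mostly in 1 direction. Contigs were tested in place of the gene lists fixed beforehand, which need gene names, and those discussed were picked after their values were seen. Among the 31 contigs with at least 3 genes, camera with a preset correlation of 0.01 found 10 whose genes ranked toward higher values on MTBE and 6 toward lower. With an estimated correlation none passed (0 toward higher and 0 toward lower, smallest adjusted p = 0.310), and 3 contigs had an unadjusted p under 0.05. The fry test called 13 contigs toward higher and 10 toward lower. It asks whether the genes of a contig change at all, not whether they change more than other genes. A fry call is therefore no sign that a contig moved as a whole. Contig 551 was called toward lower (fry adjusted p = 0.0067) with 4 genes higher, 5 lower and a median log2 fold change of +0.037. In the table, contigs 562, 570 and 560 had the highest medians of the contigs that passed, +0.64, +0.58 and +0.51 on the log2 scale relative to the median of all genes. Of the 191 genes of contig 570, 160 were higher on MTBE, 4 were lower and 27 did not pass (camera adjusted p = 1.0e-13, and adjusted p = 0.310 with an estimated correlation). Contig 560 had 50 higher and 0 lower of 60 genes, and contig 562 had 39 higher and 2 lower of 61 genes (adjusted p = 0.310 with an estimated correlation for both). Together 79.8% of the genes of these 3 contigs were higher, against 31.7% of the 3694 genes elsewhere. On ethanol the median gene of each was dim, with log2 values of 6.56 ± 0.077 on contig 570, 6.70 ± 0.111 on contig 560 and 6.95 ± 0.136 on contig 562 (SD, n = 3).

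The sizes and the order of these medians depended on the scaling and the genes tested. After quantile normalization of the table the relative medians were +0.90 for contig 562, +0.59 for contig 573, +0.41 for contig 570 and +0.39 for both contig 558 and contig 560. In quantile-normalized intensities they were +0.59 for contig 562, +0.35 for contig 573, +0.30 for contig 558, +0.27 for contig 570 and +0.21 for contig 560. Without the dimmest 25% of genes they were +1.29 for contig 562, +1.25 for contig 560, +1.23 for contig 550 and +1.21 for contig 570. With the RMA values centred per array, contig 570 (+0.77) and contig 552 (+0.68) came first. Set against random lists matched on level, the medians of 4 of the 16 contigs that passed lay inside the central range of the lists (contigs 550, 555, 559 and 574). In the table as deposited, contig 573 had a relative median of +0.35, with 71 higher and 24 lower of 131 genes (camera adjusted p = 0.012, and adjusted p = 0.328 with an estimated correlation). The 7 other contigs toward higher values, contig 573 among them, had relative medians of +0.22 to +0.40. The lowest, contig 555, was at +0.14 without ethanol sample 1 and lost its call with array weights (+0.13, camera adjusted p = 0.063). Contig 571 (+0.25) lost its call without ethanol sample 1 (+0.18, camera adjusted p = 0.079) and without ethanol sample 2 (+0.22, camera adjusted p = 0.053). Both calls were also lost in the quantile-normalized intensities and RMA values. Contig 552, for example, had 24 higher and 0 lower of 31 genes, and contig 558 had 22 higher and 2 lower of 32. Their adjusted p with an estimated correlation was 0.310 and 0.449. With the preset correlation, contig 558 lost its call in quantile-normalized intensities (camera adjusted p = 0.069) and re-normalized RMA values (camera adjusted p = 0.065). So did contig 564 (camera adjusted p = 0.091 and 0.067), and contig 550 lost its call in the RMA values (camera adjusted p = 0.071). The 6 contigs toward lower values had relative medians of -0.56 to -0.27. Contig 569 had 54 lower and 30 higher of 132 genes, contig 578 had 189 lower and 114 higher of 480, and contig 572 had 68 lower and 30 higher of 166. The adjusted p with an estimated correlation was 0.372, 0.437 and 0.310. With the preset correlation these calls also ended under some sources of the values. Contig 578 had an adjusted p of 0.075 in quantile-normalized intensities and 0.067 in both the RMA values and the table after quantile normalization. Contig 572 had 0.079 in the intensities and 0.067 in the RMA values, and contig 569 had 0.094 in the RMA values. Contig 574, which holds the longest run of falls, had 0.069 in the intensities and 0.094 in the RMA values. Contig 559 had 0.069 in the intensities. Contig 577 kept its call in both (camera adjusted p = 0.034 and 0.048) but lost it without the dimmest 25% of genes (camera adjusted p = 0.074). On contig 579, which holds 720 genes and both genes with the largest falls in the table, 237 genes were higher and 217 lower. The contig as a whole did not pass with camera (camera adjusted p = 0.613). With fry it was called toward lower (fry adjusted p = 0.011), although its median log2 fold change was +0.088.

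**Figure D3:**
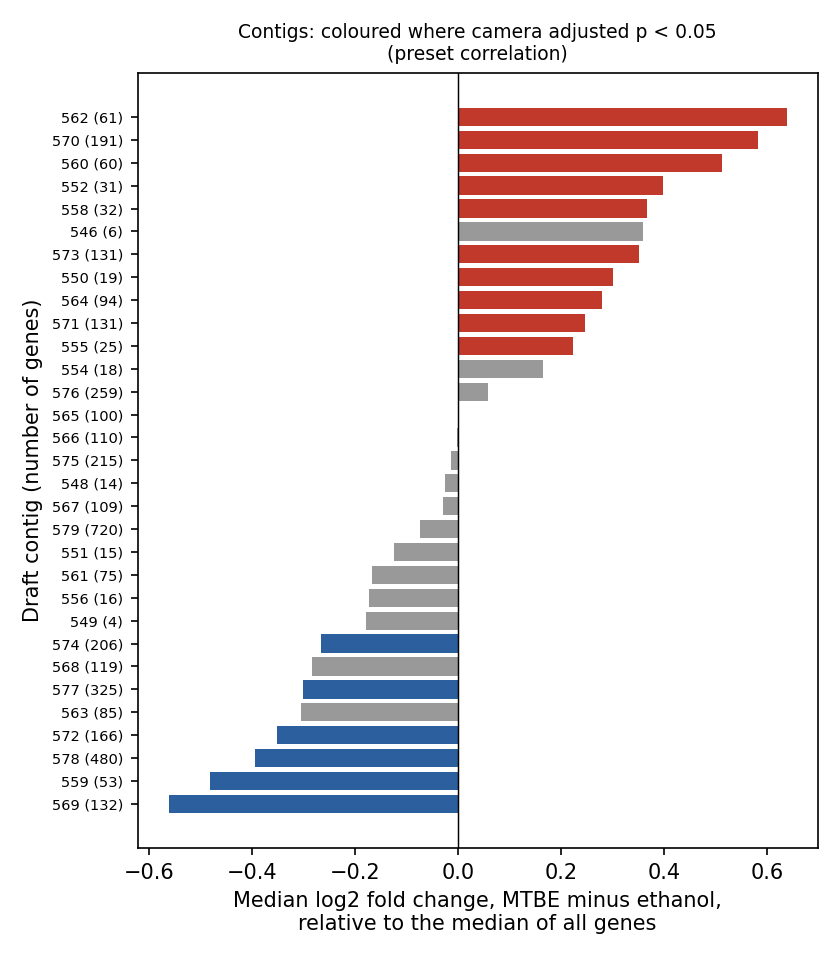
Median log2 fold change (MTBE minus ethanol) of the genes of each of the 31 contigs with at least 3 genes, relative to the median of all genes, with the number of genes in brackets. Coloured bars have a camera adjusted p under 0.05 with the preset correlation, 10 toward higher (red) and 6 toward lower (blue) values, none of which passed with an estimated correlation.

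The design also gave a comparison of repeat arrays, since each ethanol sample had 2. By their deposited RMA values the 9 arrays fell into 3 sets of 3 with a distribution of their own, the MTBE arrays (medians 5.92 to 5.93) and 2 sets with 1 array of each ethanol sample (medians 8.19 to 8.25 in set 1 and 7.83 to 7.86 in set 2). In unnormalized intensities, the rank correlation across genes between the 2 arrays of a sample was 0.764 to 0.821. Arrays of different ethanol samples were closer, with 0.918 to 0.941 within set 1 and 0.920 to 0.949 within set 2, and different samples across the sets gave 0.751 to 0.828. The 3 MTBE arrays gave 0.932 to 0.942 among themselves, 0.454 to 0.614 with set 1 and 0.564 to 0.654 with set 2. After quantile normalization, the SD across genes of the log2 difference between the 2 arrays of a sample was 0.413 to 0.470. The ethanol columns of the series table followed set 1 (r = 0.986 to 0.990 across genes) more closely than set 2 (0.817 to 0.847). Quantile-normalized intensities gave 1283 genes higher and 1218 lower on MTBE against set 1, and 1096 higher and 1086 lower against set 2. Of these, 854 were higher and 793 lower against both sets, and 41 and 14 had opposite directions. Independent lists of these lengths would share 351 and 330. Simulated unchanged groups, compared with the same 3 simulated MTBE arrays, shared 0. That says little, since groups without change are bound to give few calls at an adjusted threshold. The covariance of the 2 sets of fold changes was 0.309, against 0.0095 in the simulation, and their correlation was 0.815, against 0.495. The simulation held only the spread within sets and no offset between sets. Its values therefore cannot show how much of the overlap an offset of the MTBE arrays would give. The 3 MTBE arrays are too few to be split, so part of the overlap may come from sharing them.

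**Figure D4:**
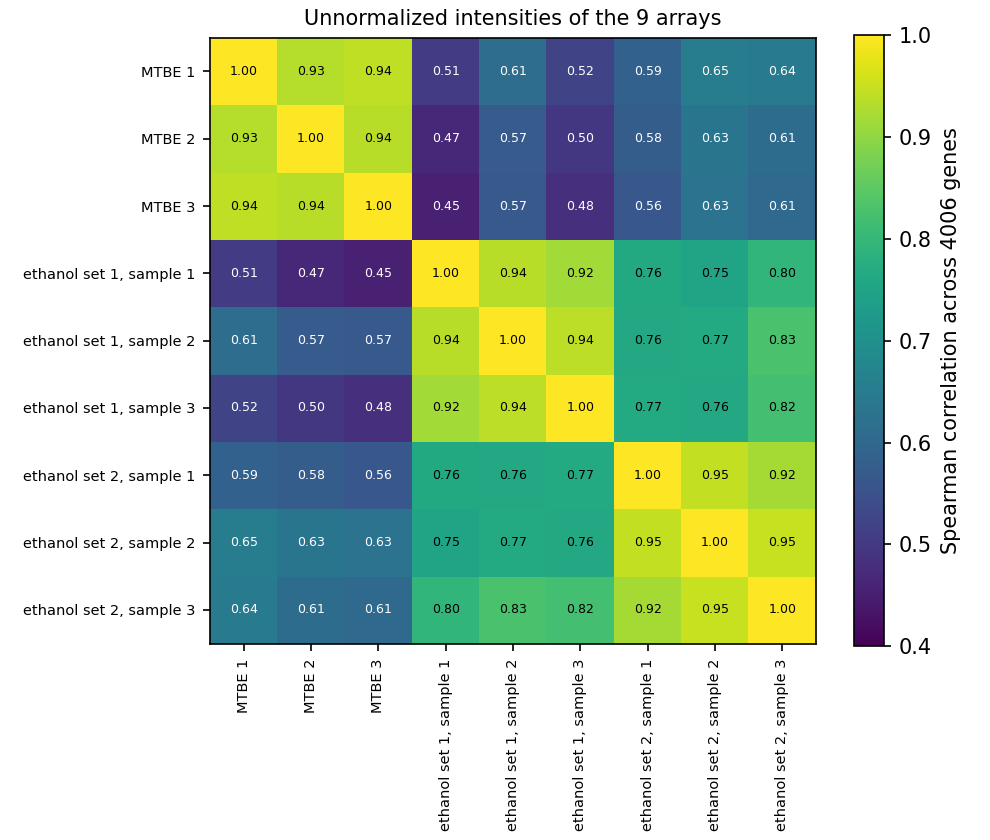
Spearman correlation across 4006 genes of unnormalized intensities for each pair of the 9 arrays, on a colour scale from 0.4 to 1. The 2 ethanol sets form separate blocks (0.918 to 0.949 within a set), and the arrays of 1 sample in different sets reach 0.764 to 0.821.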

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

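The ethanol array sets were compared after the difference between them had been seen, as were all tests in this part. Signal in data that the main comparison uses little was found in ethanol array set 2, which holds 1 array of each ethanol sample. With quantile-normalized intensities and the sample as a block, 1208 genes differed between the 2 ethanol array sets (limma, adjusted p under 0.05), 593 higher and 615 lower in set 2, and 80 and 106 of these by at least 2-fold. Both sets carry the same 3 sample labels, so no difference between groups of the study enters. Without the block 1235 genes differed, and the highest count of the other splits of these 6 arrays was 0. The real split is 1 of 10, too few for a share under 0.05. Each other split mixes the 2 sets, so their difference adds to the spread and few calls are bound to follow.

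Separate normalization or another scanner setting would leave the rank order of genes nearly intact. The highest rank correlation between the 2 arrays of a sample was 0.821 in unnormalized intensities, below the lowest within a set, 0.918, which argues against these as the whole source. Independent noise of single genes is argued against by neighbouring genes, whose differences between the sets correlated with r = 0.378, above each of 100000 shuffled orders (highest 0.064). Whether the same RNA was measured in 2 hybridization rounds stays open: the 2 arrays of a sample deviated from their set means with correlations of 0.268, -0.042 and 0.192, and other pairs across the sets reached 0.327. A difference between hybridization rounds, between RNA preparations or between cultures cannot be told apart here, and no biological explanation was tested, since the labels give none.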

How the results depend on the processing

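Settings on single or selected arrays, the random block, normexp, the centred or quantile-normalized table, the probe filter and the use of contigs and runs (with an estimated correlation and fry for contigs) were chosen after seeing the data. Across all settings except the RMA files as deposited, 810 to 1822 genes were higher and 750 to 1539 lower. The 4 named genes kept direction and call under each setting in which they were tested, with 1 exception: gene LLNL0001S00003401 with the second listed arrays. Their sizes moved with the source of the values. With intensities (quantile normalized; first listed array; second listed array; without the PMT1 array; set 1; set 2; random block), 207, 201, 147, 191, 255, 131 and 206 genes were at least 2-fold higher and 220, 214, 143, 199, 283, 158 and 214 at least 2-fold lower. Contigs toward higher numbered 6 in each and toward lower 2, 3, 2, 2, 1, 2 and 3. The second listed arrays gave 810 genes higher and 750 lower. Normexp gave 690 at least 2-fold higher and 699 lower, with 6 contigs toward higher and 2 toward lower. The RMA files quantile normalized once more gave 5 and 2 contigs, and the table after quantile normalization gave 6 and 3. The cause was not tested. Without the dimmest 25% of genes, 852 genes were higher, 1085 lower and 3 contigs lower, with fewer genes tested. The test against a fold of 1.2, which asks for more, left 890 higher and 930 lower. An estimated correlation left 0 and 0 contigs, and fry gave 10 toward lower. The RMA files as deposited gave 17 genes higher and 3940 lower, 7 and 3752 at 2-fold, and 4 and 0 contigs, and they reversed the run from gene 409 on contig 562 to -1.23. Their separate scales per group set these counts.

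Of the 2543 genes called, 1397 were called in the same direction and 166 in the opposite one with intensities of ethanol set 2, 1904 and 49 with set 1, and 1988 and 103 with re-normalized RMA values. Leaving out each sample in turn gave 1116 to 1333 genes higher and 973 to 1154 lower, 403 to 485 and 753 to 809 at 2-fold, and 9 to 11 contigs toward higher and 6 to 7 toward lower. With the replicate number as a block, 1257 genes were higher and 1097 lower, 448 and 795 at 2-fold. Samples of the same number did not deviate together (r = -0.034, -0.053 and -0.044 across genes), which gives no sign of pairing. It cannot exclude pairing, since even the 2 arrays of an ethanol sample gave only 0.268, -0.042 and 0.192. The gene lists and the megaplasmid comparison, with their alternatives, were not run. No detection calls show which dim genes lie above background.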

Other observations

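All tests in this part were chosen after the result was seen, except the comparison of the contig medians with ethanol set 2, which was written down before its outcome was seen, although the contigs had been picked by then. Of the 100 genes with the highest mean value on ethanol and the 100 highest on MTBE, 24 were shared, against 2.50 expected of independent lists. A log2 value of 12 or more was reached by 119 genes on ethanol and 37 on MTBE, 17 of them on both, on the scale of the deposited table.

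Some genes varied between replicates far more than most. The SD over the 3 samples had a median of 0.206 on ethanol and 0.157 on MTBE, but exceeded 1 for 73 genes on ethanol and 31 on MTBE. Ethanol sample 1 was farthest from the median for 65 of the 73, and 14 of the 73 lay on contig 567. MTBE sample 3 was farthest for 25 of the 31.

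The rise of contigs 562, 570 and 560 as groups, the 3 with the highest medians in the table as deposited, has a technical candidate explanation in the narrower range of the MTBE values, which would lift dim genes in general. The medians of all 3 contigs lay above the upper bound of random lists matched on level, by at least 0.194 on the log2 scale. This cannot decide the question, since the contigs were picked for their high medians and the lists draw genes independently. For 4 of the 16 contigs that passed, the median lay inside the matched range. The level remains open as an explanation for them as for contigs 562, 570 and 560. In quantile-normalized intensities the relative medians of contigs 562, 570 and 560 were 0.78, 0.28 and 0.23 against set 1. Against set 2 all 3 stayed above 0, and the smallest was 0.156 (contig 560), above the upper bound of 0.092 of random lists. These lists also draw genes independently, so the bound cannot show whether the rise against set 2 exceeds that of genes that move together. The same MTBE arrays serve against both sets. Genes of a contig are not independent, and with an estimated correlation the adjusted p was 0.310 for each contig. A response of these regions to the carbon source is a hypothesis that stays open, as do differences between hybridization rounds, since MTBE and ethanol arrays share no set.

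More genes fell than rose at 2-fold or more on MTBE, and the narrower range of the MTBE arrays may account for this. In unnormalized intensities the distance from the median to the 95th percentile was 0.86 to 1.06 on the log2 scale on MTBE arrays, 2.14 to 2.56 in ethanol set 1 and 1.55 to 1.78 in set 2. When the table was given 1 distribution, the share of higher genes among those changed at least 2-fold was 50.2%, a setting that itself moves the directions toward balance. The range goes with the group on each array, so a narrower range of the arrays and a true fall of strongly expressed genes cannot be told apart.

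For the main comparison, 2543 genes changed, 1244 by at least 2-fold, and the highest count among the other splits of the 6 samples was 0 for both. The real split is 1 of 10 in each case, too few for a share under 0.05. Each other split mixes MTBE and ethanol samples, so the difference between the groups adds to the spread and few calls are bound to follow.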
